A study of Acinetobacter venetianus RAG-1 = CIP 110063 with 9 samples.

How the data were processed

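RNA was sequenced from Acinetobacter venetianus RAG-1, an oil-degrading bacterium known for the emulsifier emulsan, fed with 1 of 3 carbon sources. The carbon sources were dodecane (a 12-carbon alkane, 1% v/v), dodecanol (its primary alcohol, 5 mM) and sodium acetate (0.2%), with 3 libraries each. The doses are in different units and were not matched between the compounds. Per the labels' protocols, cells grew in 50 ml of mineral medium with ferrous chloride (0.05 mg/ml), were collected in the middle of exponential growth and gave RNA with integrity numbers above 9.6. DNase treatment, depletion of ribosomal RNA, 18 cycles of PCR and single reads of 50 bases followed, per the labels' protocols. The labels describe growth in triplicate flasks and do not say whether the flasks had separate starter cultures or days, so p-values measure the spread between these flasks.

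The authors deposited read counts per gene, which are whole numbers without normalization. Per the file headers, reads were trimmed and those that aligned to ribosomal RNA were removed before counting. CASAVA 1.18 and edgeR are named in the submitters' processing notes. The aligner, the counting program, its treatment of strand and the genome build are not given in the sources used here. Each of the 3 deposited tables holds 3223 genes on 5 scaffolds. The gene number, the product name and the positions are those of the tables, with starts printed 1-based. Whole-codon lengths in all 3223 genes fit a start that counts from 0, and the lengths are coding lengths without untranslated regions. The tables name no strand, so reads from overlapping genes on opposite strands cannot be assigned here. The deposited counts of unique reads and of total reads were equal in all 29007 combinations of gene and library. The deposited tables further hold p-values and signed fold changes from the authors' own comparisons, per the file headers made with the EDGE test with tagwise dispersions, and these were used only to count calls. A further 72 columns of values per sample were not used.

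Total counts in the 3 dodecane libraries ran from 9532930 (AK1) to 12838195 (AK3), and values of 1 of them are not reported singly here. They were 12518954, 10355467 and 12193699 in the dodecanol libraries AK4, AK5 and AK6, and 2571475, 5785655 and 4772808 in the acetate libraries AK7, AK8 and AK9. A gene without reads could have had up to 3 counts, which is 0.315 CPM (counts scaled to library size) in AK1 and 1.17 CPM in AK7, the shallowest library, before TMM factors. This floor covers counting error only, since PCR copies are not independent molecules. Ratios of chi-square to degrees of freedom between libraries of a group ran from 12.0 to 436, so no pair was a repeat of the same library.

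Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The filterByExpr function kept 3178 genes and removed 45, of which 6 had no read. All 9 libraries entered a single model with TMM scaling and robust quasi-likelihood dispersions, and the quasi-likelihood F test gave each contrast. Adjusted p-values are Benjamini-Hochberg values over the 3178 genes, and a gene passed at 0.05. Printed log2 fold changes are those of edgeR, shrunk slightly toward 0 by its prior count. The standard error (SE) of a log2 fold change is the size of the unshrunk change divided by the square root of F. Intervals are 95% and set this SE around the printed change. TMM factors ran from 1.21 to 1.44 for dodecane, from 0.732 to 0.893 for dodecanol and from 0.895 to 0.986 for acetate. CPM values are printed as mean ± SD over n = 3 libraries with these factors.

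Gene groups were 29 lists set by search terms on the product names before the data were examined, as were the comparisons, the tests and the rule for naming genes. They cover alkane oxidation, alcohol and aldehyde dehydrogenases, fatty acid activation and beta-oxidation, outer membrane proteins, capsular and emulsan polysaccharide, type IV pili, wax ester synthesis, the glyoxylate bypass, acetate uptake and activation, gluconeogenesis, the TCA cycle, the respiratory chain with ATP synthase, ribosomal proteins, iron acquisition and storage, oxidative stress defence, chaperones and heat shock, multidrug efflux, fatty acid synthesis, lipases and esterases, sulfur acquisition, phosphate acquisition, type VI secretion, mobile elements, transcription regulators, PQQ and quinoproteins, adhesins and biofilm, aromatic compound degradation, the methylcitrate cycle, and ribosomal and transfer RNA genes. No product name matched type VI secretion or ribosomal and transfer RNA, so these held 0 genes, and wax ester synthesis held 1. The other 26 were tested with camera against all other genes at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26. The search terms also caught genes of other function, among them 2-isopropylmalate synthase (peg.644) in the glyoxylate bypass, 3-isopropylmalate dehydrogenase (peg.237) in the TCA cycle, the biosynthetic anthranilate and para-aminobenzoate synthases (peg.2838 and peg.1726) in aromatic compound degradation, a dye-decolorizing peroxidase (peg.2546) among capsular genes, the TolB protein (peg.1270) among iron genes, and a peptidyl-prolyl isomerase (peg.3142) among mobile elements. Overlaps of gene groups with lists were tested with Fisher's exact test, adjusted over the 26 lists.

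The rule for naming genes took, per comparison, every alkane oxidation gene. It added the 8 genes with the greatest rise and the 8 with the greatest fall among those with an adjusted p under 0.05, a mean of at least 10 CPM, no overlap between the 3 and 3 libraries and a product name other than hypothetical. For each other list it took up to 3 members with the smallest adjusted p, plus up to 2 that did not pass where fewer than 3 passed. The text names part of these. Unnamed products passed over on the way numbered 8 higher and 3 lower for dodecane against acetate, 1 and 4 for dodecanol against acetate, and 9 and 1 for dodecane against dodecanol. The elongation factor Tu genes (peg.92 and peg.1535) are among 8 genes whose protein is identical to another in the table, so their counts are uncertain. The alkane-1 monooxygenases share 244 of 396 aligned residues (61.6%, aligned with Biopython 1.88).

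The code was tested on simulated counts in which 200 of 3178 genes were changed, with 10 draws per comparison. Equal numbers were raised and lowered, and genes were drawn independently. In the real data 45.3% to 62.7% of genes were called, so the simulated shares do not test scaling under changes that broad. The code recovered 64.1%, 65.5% and 67.2% of genes changed 2-fold, for dodecane against acetate, dodecanol against acetate and dodecane against dodecanol. Of genes changed 4-fold it recovered 94.1%, 95.1% and 95.5%. The mean share of false calls was 4.47%, 4.63% and 6.17%, with a highest draw of 7.78%, 9.04% and 11.9%, so for dodecane against dodecanol the mean itself lay above the nominal level, and for all 3 comparisons single draws did. Alternatives were RLE scaling, library size alone, 2 other low-count filters, DESeq2 1.42.0, limma-voom, fits of 2 groups, each library left out in turn, no fold limit for the genes shared by or setting apart the carbon sources, the authors' deposited calls, and camera with an estimated correlation or fry for the lists. After the data were seen, thinning of all libraries to the total of AK7 was added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.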

Results

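Transcripts of Acinetobacter venetianus RAG-1 were counted in 9 libraries, 3 each from cells grown on dodecane, dodecanol or sodium acetate. Acetate served as the carbon source with which both long-chain compounds were compared. Totals lay between 9532930 and 12838195 counts in the dodecane and dodecanol libraries and between 2571475 and 5785655 in the acetate libraries, so low genes were measured less precisely on acetate. On log2 CPM, the first principal component held 51.9% of the variance and parted dodecane from the rest, and the second held 31.1% and parted dodecanol from acetate. Dodecane library AK3 stood apart at -52.1 on the first component, against -38.6 for AK1. The biological coefficient of variation was 17.6% within acetate, 21.9% within dodecane and 27.0% within dodecanol.

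**Figure D1:**
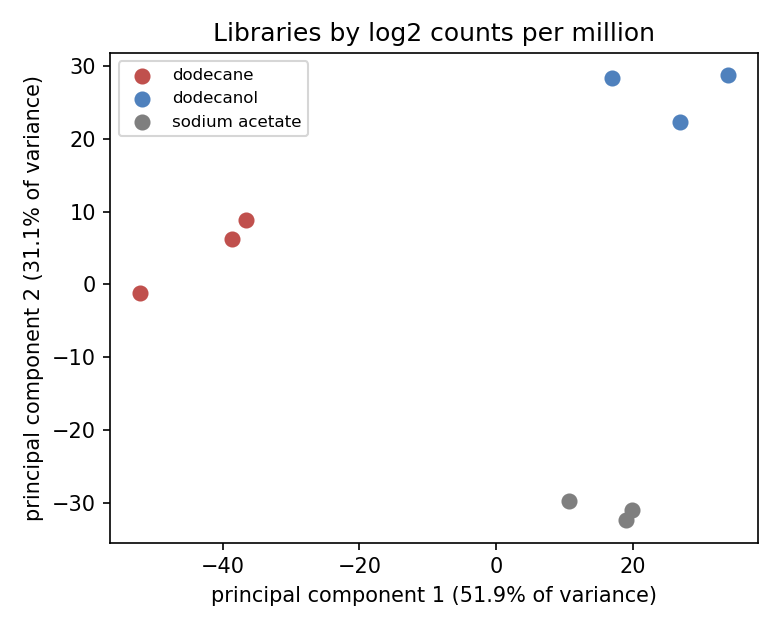
Each point is a library, placed by its first principal component (horizontal axis, 51.9% of the variance) and second principal component (vertical axis, 31.1%) of log2 CPM, coloured by carbon source. The 3 dodecane libraries lie to the left of all others, with AK3 the farthest out at -52.1.

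Dodecane against acetate asks which genes the bacterium uses for taking up and oxidising the alkane. An alkane-1 monooxygenase gene, peg.2514, whose product adds the first hydroxyl group to an alkane, rose 153-fold on dodecane (log2 fold change 7.25, SE 0.42, adjusted p = 5.65e-08), from 201 ± 104 to 30679 ± 6669 CPM (mean ± SD, n = 3 each). It lies at positions 1159329 to 1160525 of scaffold NZ_KB849558. The other alkane-1 monooxygenase gene, peg.2111 (732332 to 733573 of the same scaffold), rose by a log2 fold change of 4.94 (SE 0.47, adjusted p = 2.16e-05), from 19.3 ± 10.5 to 569 ± 216 CPM. An alcohol dehydrogenase gene, peg.2264, and an aldehyde dehydrogenase gene, peg.2266, whose products can carry out the next oxidation steps, rose by 6.77 (SE 0.69) and 5.17 (SE 0.86) on the log2 scale, with adjusted p = 5.23e-05 and 0.00129. In contrast, isocitrate lyase (peg.2800), the first enzyme of the glyoxylate bypass, fell by 4.43 on the log2 scale (SE 0.31, adjusted p = 2.07e-07), from 12570 ± 1190 CPM on acetate to 583 ± 197 CPM on dodecane.

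Of the 5 alkane oxidation genes, 3 rose and 2 fell on dodecane, and the counts were equal when adjusted over the list alone. The third that rose was peg.2776 (log2 fold change 1.08, adjusted p = 0.00230), from 12.1 ± 2.2 to 25.2 ± 3.1 CPM. It is named for a rubredoxin-NAD+ reductase, a type of enzyme that can supply electrons for alkane hydroxylation. Whether peg.2776 does so was not tested. The rubredoxin gene peg.2811 (-1.53, adjusted p = 0.00145) and another reductase gene, peg.2812 (-0.84, adjusted p = 0.00180), fell. They had 14.1 ± 0.6 and 160 ± 11.5 CPM on acetate and 4.87 ± 0.28 and 89.4 ± 11.6 CPM on dodecane. Under scaling to library size alone peg.2812 did not pass (-0.35). Among 16 alcohol and aldehyde dehydrogenases, 7 rose, 2 fell and 7 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Besides peg.2264, the aldehyde dehydrogenase peg.1064 rose (log2 fold change 1.46), and the alcohol dehydrogenase peg.1041 fell (-1.65). The SDs of peg.2264 (3186 ± 2786 CPM on dodecane) and peg.2266 (7415 ± 8274 CPM) rested on library AK3. Without that library their log2 fold changes were 5.79 and 3.69, with adjusted p = 9.35e-08 and 4.44e-06. Fatty acid activation and beta-oxidation genes went both ways: 8 rose, 11 fell and 11 of 30 did not pass, with 8 and 12 when adjusted over the list alone. An acyl-CoA dehydrogenase gene, peg.2615, rose by 2.20 (log2, SE 0.16), while peg.479 fell by 1.25 (SE 0.15). The product name of peg.479 joins an enoyl-CoA hydratase of isoleucine degradation with a 3-hydroxyacyl-CoA dehydrogenase and a 3-hydroxybutyryl-CoA epimerase.

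Most genes of the respiratory chain with ATP synthase, of ribosomal proteins and of the TCA cycle were lower on dodecane. Of 29 respiratory chain and ATP synthase genes, 28 fell and 1 rose (median log2 fold change -1.34), and the counts were equal when adjusted over the list alone. ATP synthase gamma chain (peg.3055, -2.71, SE 0.25) and cytochrome o ubiquinol oxidase subunit III (peg.1387, -2.43, SE 0.22) were among them. The list was called lower than other genes by camera (adjusted p = 3.40e-11), and not with an estimated correlation (adjusted p = 0.396 with an estimated correlation). Of 57 ribosomal protein genes, 37 fell, 8 rose and 12 did not pass, and 40 fell and 8 rose when adjusted over the list alone (median -1.09). L36p (peg.691) fell by 2.14 and S15p (peg.169) rose by 1.47 on the log2 scale. The camera call for this list had an adjusted p = 7.36e-06, against an adjusted p = 0.50 with an estimated correlation. In the TCA cycle, 13 of 19 genes fell, 3 rose and 3 did not pass, and 14 fell and 3 rose when adjusted over the list alone. Citrate synthase (peg.313, -2.71, SE 0.22) and aconitate hydratase 2 (peg.2449, -3.31, SE 0.28) fell, and malate:quinone oxidoreductase (peg.1686) rose by 2.39 (SE 0.22). Camera called the TCA cycle lower at an adjusted p = 0.00118, with an adjusted p = 0.465 with an estimated correlation.

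All 3 genes of the glyoxylate bypass list fell, also when adjusted over the list alone: isocitrate lyase, malate synthase G (peg.2347, -1.39, SE 0.21) and 2-isopropylmalate synthase (peg.644, -0.92), which acts in leucine synthesis. All 5 methylcitrate cycle genes, which serve propionyl-CoA breakdown, fell in both counts, among them methylisocitrate lyase (peg.3118, -1.68). They include aconitate hydratase 2 (peg.2449), which is also in the TCA cycle list, so the calls of these lists are not separate. Camera called the glyoxylate bypass and methylcitrate lists lower (adjusted p = 0.00194 and 0.000121), and not with an estimated correlation (adjusted p = 0.396 for both with an estimated correlation). Acetate uptake and activation genes split: 4 of 6 fell, including phosphate acetyltransferase (peg.633, -2.20) and acetate kinase (peg.632, -2.01), and 1 rose, the acetyl-coenzyme A synthetase peg.3093 (2.28), with 4 and 2 when adjusted over the list alone. Of 15 gluconeogenesis genes, 9 fell, 1 rose and 5 did not pass, as in the counts adjusted over the list alone, and phosphoenolpyruvate carboxykinase (peg.1143) fell by 1.67 (SE 0.28).

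Type IV pilus genes, which serve surface attachment and twitching motility, fell in 24 of 29 cases and rose in 4, with 25 and 4 when adjusted over the list alone (median -1.07). The twitching motility gene pilT (peg.1505) fell by 2.38 (SE 0.15), and the tip protein gene pilY1 (peg.1725) rose by 2.26 (SE 0.19). Camera gave an adjusted p = 3.37e-06 for this list and an adjusted p = 0.396 with an estimated correlation. Oxidative stress genes fell in 14 of 21 cases and rose in 0, in both counts, and the alkyl hydroperoxide reductase peg.2512 dropped by 3.83 (SE 0.27), to 589 ± 128 from 8360 ± 550 CPM. That list had an adjusted p = 0.000199 by camera and an adjusted p = 0.396 with an estimated correlation. The PQQ and quinoprotein list had 2 of 4 genes up in both counts, with a PQQ synthesis gene (peg.2169) at 2.90 (SE 0.19) and the PQQ-dependent quinate dehydrogenase peg.2584 at 1.56 (SE 0.20). The PQQ-dependent glucose dehydrogenase peg.472 did not pass (0.10, SE 0.25, adjusted p = 0.752), except under library size alone (0.63). Aromatic compound degradation had 13 of 24 genes up and 0 down, and 14 up when adjusted over the list alone. Among these, muconate cycloisomerase (peg.2250) rose by 2.47, from 2.49 ± 1.06 CPM on acetate. That level is near the floor of 1.17 CPM in AK7, so the size of this rise is uncertain. Camera called the PQQ and aromatic lists higher (adjusted p = 0.0352 and 0.0223), with adjusted p = 0.396 for both with an estimated correlation. Without library AK3 both calls ended. The aromatic call also ended under library size alone, and the PQQ call also ended without acetate library AK7.

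Genes of other groups moved in part, and camera did not call these lists. Heat shock genes fell in 12 of 27 cases and rose in 5, in both counts, with the chaperonin GroEL (peg.1148) at -3.16 (SE 0.34) and HtpG (peg.107) at -3.19 (SE 0.29). Outer membrane protein genes rose in 8 of 23 cases and fell in 8, with 8 and 9 when adjusted over the list alone. Their median of -0.09 turned to 0.41 under library size alone, their mean was 0.004 and the camera direction was down. OmpW (peg.105) fell by 2.52 (SE 0.33), and an OmpA gene (peg.2886) rose by 1.85 (SE 0.20). Of 22 capsular and emulsan genes, 10 fell and 4 rose in both counts. Of 32 iron genes, 14 rose and 8 fell in both counts, with a coprogen receptor (peg.1141) at 3.06 and a TonB-dependent receptor (peg.2139) at -2.93. Multidrug efflux had 20 of 41 genes up and 7 down, with 22 and 7 when adjusted over the list alone. Fatty acid synthesis had 8 of 24 up and 11 down in both counts. Of 16 lipases and esterases, 5 rose and 3 fell in both counts, and a lipase precursor gene (peg.2463) rose 15.5-fold (log2 fold change 3.96, SE 0.30). Sulfur acquisition had 5 of 24 up and 6 down, and phosphate acquisition 4 of 11 up and 1 down, in both counts. Of 21 mobile element genes, 14 rose and 3 fell, with 14 and 4 when adjusted over the list alone. Transcription regulators had 42 of 143 up and 22 down, with 39 and 20 when adjusted over the list alone, and adhesins and biofilm 1 of 6 up and 3 down in both counts. The wax ester synthase gene, peg.400, which makes storage lipid, did not pass (0.22, 95% interval -0.14 to 0.59), except under library size alone (0.71). Under library size alone the medians of beta-oxidation (-0.31), capsular (-0.38), heat shock (-0.37), sulfur (-0.07) and adhesin genes (-0.16) turned positive.

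Outside the lists, genes for the compatible solute ectoine stood among the greatest rises. The ectoine regulator gene (peg.2961) rose by 4.91 (log2, SE 0.22) and diaminobutyric acid acetyltransferase (peg.2962) by 4.49 (SE 0.24). Fumarylacetoacetase (peg.2054), of tyrosine breakdown, rose by 5.68 (SE 0.28) and the glyoxalase family gene peg.2052 by 4.54 (SE 0.42), or by 5.47 without acetate library AK8. On acetate peg.2052 had 2.42 ± 2.17 CPM, near the floor of 1.17 CPM in AK7, so the size of its rise is uncertain. Glutamate dehydrogenase (peg.1408) fell by 3.74 (SE 0.23), and the efflux genes peg.1457 and peg.1456 fell by 4.22 (SE 0.73) and 3.29 (SE 0.50). Without library AK3 these were -5.48 and -4.04.

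In all, edgeR's test called 1737 of 3178 genes (54.7%), of which 909 were higher and 828 lower on dodecane. At least 2-fold changes numbered 1017, with 579 higher and 438 lower. In 66.0% of tested genes the libraries of the groups did not overlap, where chance gives 10%. Under library size alone 1480 genes were higher and 415 lower, since that scaling moved the median of all genes by 0.50 (log2), so directions hold relative to the bulk of genes. The authors' deposited table called 1857 genes, of which 1703 were called here in the same direction and 0 in the opposite.

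**Figure D2:**
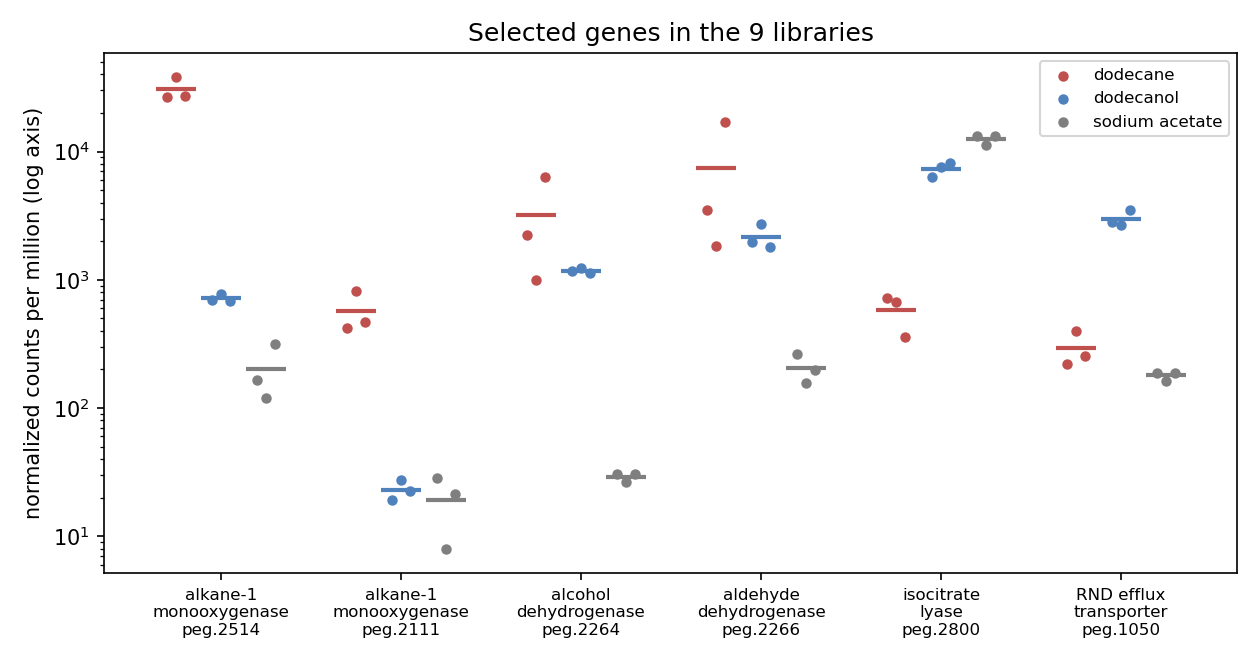
Points are the CPM of single libraries (vertical log axis) and bars their means (n = 3) for 6 genes (horizontal axis), coloured by carbon source. The alkane-1 monooxygenase peg.2514 reached 30679 CPM on dodecane, 721 on dodecanol and 201 on acetate.

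Dodecanol against acetate asks which genes respond to the alcohol, the first oxidation product of the alkane. The alcohol dehydrogenase gene peg.2264 rose by 5.34 on the log2 scale (SE 0.64, adjusted p = 0.000181), from 29.2 ± 2.5 to 1180 ± 55 CPM (mean ± SD, n = 3 each), and the aldehyde dehydrogenase gene peg.2266 rose by 3.39 (SE 0.79, adjusted p = 0.00886). The efflux genes peg.1050 and peg.1051 rose 16.7-fold and 21.4-fold (log2 fold changes 4.06, SE 0.26, and 4.42, SE 0.29; adjusted p = 1.95e-07 and 1.96e-07). The major pilin gene pilA (peg.812) fell by 3.88 (SE 0.77, adjusted p = 0.00489), from 1960 ± 188 to 133 ± 66 CPM. The alkane-1 monooxygenase peg.2514 rose 3.59-fold (log2 fold change 1.84, SE 0.33, adjusted p = 0.000638), while peg.2111 did not pass (0.32, 95% interval -0.63 to 1.27, adjusted p = 0.578).

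Of the 5 alkane oxidation genes, 1 rose, 1 fell and 3 did not pass, and 2 rose and 1 fell when adjusted over the list alone. The gene that fell was peg.2776 (-0.67, adjusted p = 0.0451). Its call was lost under 11 of the other settings, with values of -0.53 to -0.77. Rubredoxin (peg.2811) was at -0.35 (adjusted p = 0.380) and peg.2812 at 0.46 (adjusted p = 0.0559), which passed without AK3 (0.46) or AK4 (0.61). Among the alcohol and aldehyde dehydrogenases, 4 of 16 rose and 6 fell in both counts, with peg.1041 at -1.32 and peg.1064 at -1.41. Their median was -0.19, their mean 0.30 and the camera direction down. Beta-oxidation genes rose in 9 of 30 cases and fell in 10, with 9 and 11 when adjusted over the list alone, and the acyl-CoA dehydrogenase peg.517 rose by 2.41 (SE 0.31), to 2949 ± 700 CPM.

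Type IV pilus genes fell in 26 of 29 cases and 3 did not pass, with 26 down and 1 up when adjusted over the list alone (median -1.86). The minor pilin genes pilV (peg.797) and pilW (peg.796) fell by 3.68 (SE 0.29) and 3.56 (SE 0.26). Camera called the list lower at an adjusted p = 2.24e-18, which became an adjusted p = 0.465 with an estimated correlation. Ribosomal protein genes rose in 15 of 57 cases and fell in 0, in both counts, among them S20p (peg.1792, 2.26) and L32p (peg.1576, 1.79). Camera called them higher at an adjusted p = 0.0255, against an adjusted p = 0.896 with an estimated correlation, and the call ended without library AK6 or AK8 and with fry (adjusted p = 0.11). No other list was called. Multidrug efflux had 15 of 41 genes up and 9 down in both counts, and a further RND efflux gene, peg.346, rose by 2.09 (SE 0.19). Adhesins had 4 of 6 up and 1 down, with 5 and 1 when adjusted over the list alone, such as the fimbrial genes peg.1981 (2.36) and peg.1985 (2.34). Phosphate acquisition had 6 of 11 up and 1 down in both counts, with a phosphate transporter (peg.1223) at 1.94 (SE 0.16). The respiratory list had 2 of 29 up and 3 down, with 2 and 2 when adjusted over the list alone, including ATP synthase subunit a (peg.3060, 0.96) and ATP synthase protein I (peg.3061, 2.69). Acetate uptake had 5 of 6 down in both counts, with the acetate permease ActP (peg.3034) at -2.27 (SE 0.41). Isocitrate lyase (peg.2800) fell by 0.77 (SE 0.27, adjusted p = 0.0323), a call that 6 other settings did not keep, with values of -0.67 to -0.86. Malate synthase G (peg.2347) did not pass (0.004, SE 0.20). Iron genes rose in 12 of 32 cases and fell in 5 in both counts, with ferrous iron transporter genes peg.64 and peg.65 at 3.31 and 2.05. Heat shock genes rose in 5 of 27 cases and fell in 5, with 5 and 4 when adjusted over the list alone, and GrpE (peg.3182) rose by 1.07. Their median was -0.11 and mean -0.08, and the camera direction was up. Outer membrane genes rose in 6 of 23 cases and fell in 6 in both counts, with OmpW (peg.105) at -3.64 (SE 0.34) and the fatty acid transporter peg.1722 at -2.25 (SE 0.25). Their median of 0.10 turned to -0.07 under library size alone, and their mean was -0.22. Oxidative stress genes rose in 3 of 21 cases and fell in 8, TCA cycle genes rose in 3 of 19 and fell in 4, gluconeogenesis genes rose in 4 of 15 and fell in 2, and capsular genes rose in 5 of 22 and fell in 1, all in both counts. Catalase (peg.2027, -1.74) and malate:quinone oxidoreductase (peg.1686, 1.91) were among them. Transcription regulators had 20 of 143 up and 39 down, with 20 and 38 when adjusted over the list alone, and aromatic degradation genes had 3 of 24 up and 5 down, with 3 and 1 when adjusted over the list alone. Fatty acid synthesis genes rose in 7 of 24 cases and fell in 6 in both counts, with a median of 0.01 that turned to -0.17 under library size alone and a mean of -0.10.

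Other great changes were a rise of the ectoine regulator gene peg.2961 by 3.56 (SE 0.21) and falls of a fatty acid synthesis reductase, peg.854 (-5.19, SE 0.26), and of the efflux genes peg.1457 (-5.67, SE 0.79) and peg.1456 (-4.18, SE 0.52). Values that moved with 1 library were peg.803, a bacterioferritin-associated ferredoxin (4.73, or 4.09 without AK4), and the metal resistance gene peg.2870 (3.62, or 2.81 without AK5). The membrane protein gene peg.1111 also moved (-4.05, or -2.48 without AK8). On acetate peg.803 had 2.26 ± 0.94 CPM, near the floor of 1.17 CPM in AK7, so the size of its rise is uncertain. The call of peg.2870 was lost without AK4, AK7, AK8 or AK9 at folds about as large (log2 3.42 to 3.91) and with limma-voom (2.95), and that of peg.1111 without AK4 (-3.93) and in the fit of 2 groups (-4.05). The wax ester synthase gene peg.400 did not pass (-0.03, 95% interval -0.39 to 0.34). In all, 1441 of 3178 genes (45.3%) were called, 701 higher and 740 lower on dodecanol, and 764 at least 2-fold (342 and 422). In 55.0% of tested genes the groups did not overlap, against 10% by chance. Under library size alone 488 were higher and 826 lower, with the median of all genes moved by -0.18. The authors' deposited table called 1346 genes, 1305 of them called here in the same direction.

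Dodecane against dodecanol compares the alkane with its alcohol, at doses of 1% v/v and 5 mM that were not matched. Both alkane-1 monooxygenases rose on dodecane, peg.2514 by 5.41 (log2, SE 0.39, adjusted p = 2.63e-07; 30679 ± 6669 against 721 ± 53 CPM, n = 3 each) and peg.2111 by 4.62 (SE 0.45, adjusted p = 2.05e-05). The lipase precursor gene peg.2463 rose 27.2-fold (4.77, SE 0.31, adjusted p = 1.53e-07), and fumarylacetoacetase (peg.2054) rose 54.1-fold (5.76, SE 0.27, adjusted p = 9.87e-09). Isocitrate lyase (peg.2800) fell by 3.66 (SE 0.30, adjusted p = 7.98e-07), and the fimbrial protein gene peg.1985 fell by 3.94 (SE 0.39, adjusted p = 3.49e-06). For peg.2264 and peg.2266, named here after their values were seen, the alcohol dehydrogenase passed (1.43, SE 0.54, adjusted p = 0.0425) with overlapping libraries. This call was lost in 8 other settings, at 0.45 without AK3 and at 1.01 (limma-voom) to 1.47 (without AK5) in the other 7. The aldehyde dehydrogenase did not pass (1.78, SE 0.74, adjusted p = 0.065) and passed in 4 other settings, at 1.68 (DESeq2) to 2.54 (library size alone).

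All 5 alkane oxidation genes differed in both counts: 3 were higher on dodecane, peg.2776 (1.75) being the third, and 2 lower, peg.2811 (-1.18) and peg.2812 (-1.30). Under library size alone peg.2811 did not pass (-0.49). Respiratory chain and ATP synthase genes fell in 24 of 29 cases, 25 when adjusted over the list alone, with ATP synthase delta chain (peg.3057) at -2.91 (SE 0.27). Camera called the list at an adjusted p = 2.69e-12, and with an estimated correlation its adjusted p = 0.442. Ribosomal protein genes fell in 49 of 57 cases and rose in 1, in both counts, with S8p (peg.698) at -1.71 (adjusted p = 1.60e-11 by camera, adjusted p = 0.442 with an estimated correlation). Gluconeogenesis had 10 of 15 down and 1 up, aromatic compound degradation 18 of 24 up and 1 down, the PQQ list 3 of 4 up, and the methylcitrate cycle 5 of 5 down, all in both counts. Phosphoenolpyruvate carboxykinase (peg.1143, -2.58), the 4-hydroxybenzoate transporter (peg.2591, 2.44) and the PQQ synthesis gene peg.2169 (2.64) were among these. Camera called these 4 lists at adjusted p = 0.0191, 0.0120, 0.0340 and 0.0191, and all had an adjusted p = 0.442 with an estimated correlation. The PQQ call ended without AK4.

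Type IV pilus genes were higher on dodecane in 16 of 29 cases and lower in 1, in both counts (adjusted p = 0.0204 by camera, adjusted p = 0.483 with an estimated correlation), and both pilY1 genes rose, peg.1725 by 3.65 and peg.1623 by 3.05. Capsular genes fell in 16 of 22 cases and rose in 3 in both counts, with a median of -0.68 that became 0.02 under library size alone (adjusted p = 0.0204 by camera, adjusted p = 0.442 with an estimated correlation). The TCA cycle had 13 of 19 down and 3 up, with 14 and 4 when adjusted over the list alone, and a median of -0.66 that became 0.01 under library size alone. Oxidative stress genes had 10 of 21 down and 2 up in both counts, and a median of -0.37 that became 0.30 under library size alone. For both lists camera gave an adjusted p = 0.0209, and an adjusted p = 0.483 with an estimated correlation. Relative to all genes these 3 lists stayed lower under library size alone, at -0.79 for capsular, -0.79 for TCA cycle and -0.51 for oxidative stress genes, and all 11 list calls were kept there. Citrate synthase (peg.313, -2.45) and alkyl hydroperoxide reductase (peg.2512, -3.69) fell. Transcription regulators rose in 50 of 143 cases and fell in 9, with 50 and 8 when adjusted over the list alone (adjusted p = 0.0369 by camera, adjusted p = 0.483 with an estimated correlation), a call that ended without AK3 or AK6. Multidrug efflux genes had 15 of 41 up and 10 down in both counts, a median of 0.49, a mean of 0.07 and a camera direction of down, without a call. The efflux genes peg.1050 and peg.1051 fell by 3.36 and 3.32 on dodecane. Alcohol and aldehyde dehydrogenases had 10 of 16 up and 3 down, with 11 and 4 when adjusted over the list alone, among them peg.1064 (2.87) and the alcohol dehydrogenase peg.329 (-2.27). Lipases had 7 of 16 up and 3 down in both counts, and sulfur genes 2 of 24 up and 6 down, with 1 and 6 when adjusted over the list alone, a median of 0.13 and a mean of -0.03. Acetate uptake genes had 2 of 6 up and 2 down in both counts, with a median of -0.29, a mean of 0.27 and a camera direction of up. The median turned to 0.44 under library size alone. The negative medians of beta-oxidation (-0.05), iron (-0.09), heat shock (-0.37), fatty acid synthesis (-0.46), phosphate (-0.28) and adhesin genes (-0.66) also turned positive there, and none of these lists was called. The chaperonin gene peg.1148 fell by 3.34 (SE 0.34) and malonate decarboxylase alpha subunit (peg.1478) rose by 4.53 (SE 0.21). A gene named for the glycine cleavage P protein, peg.1070, which starts at position 1 of its scaffold, rose by 5.23 (SE 0.59), or 4.60 without AK3. The wax ester synthase gene peg.400 did not pass (0.25, 95% interval -0.11 to 0.61), except under library size alone (0.92).

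In all, 1994 of 3178 genes (62.7%) were called between dodecane and dodecanol, 1066 higher and 928 lower on dodecane, and 1215 at least 2-fold (724 and 491). In 69.9% of tested genes the groups did not overlap, against 10% by chance. Under library size alone 1814 were higher and 397 lower, with the median of all genes moved by 0.68. The authors' deposited table called 1923 genes, 1840 of them called here in the same direction.

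**Figure D3:**
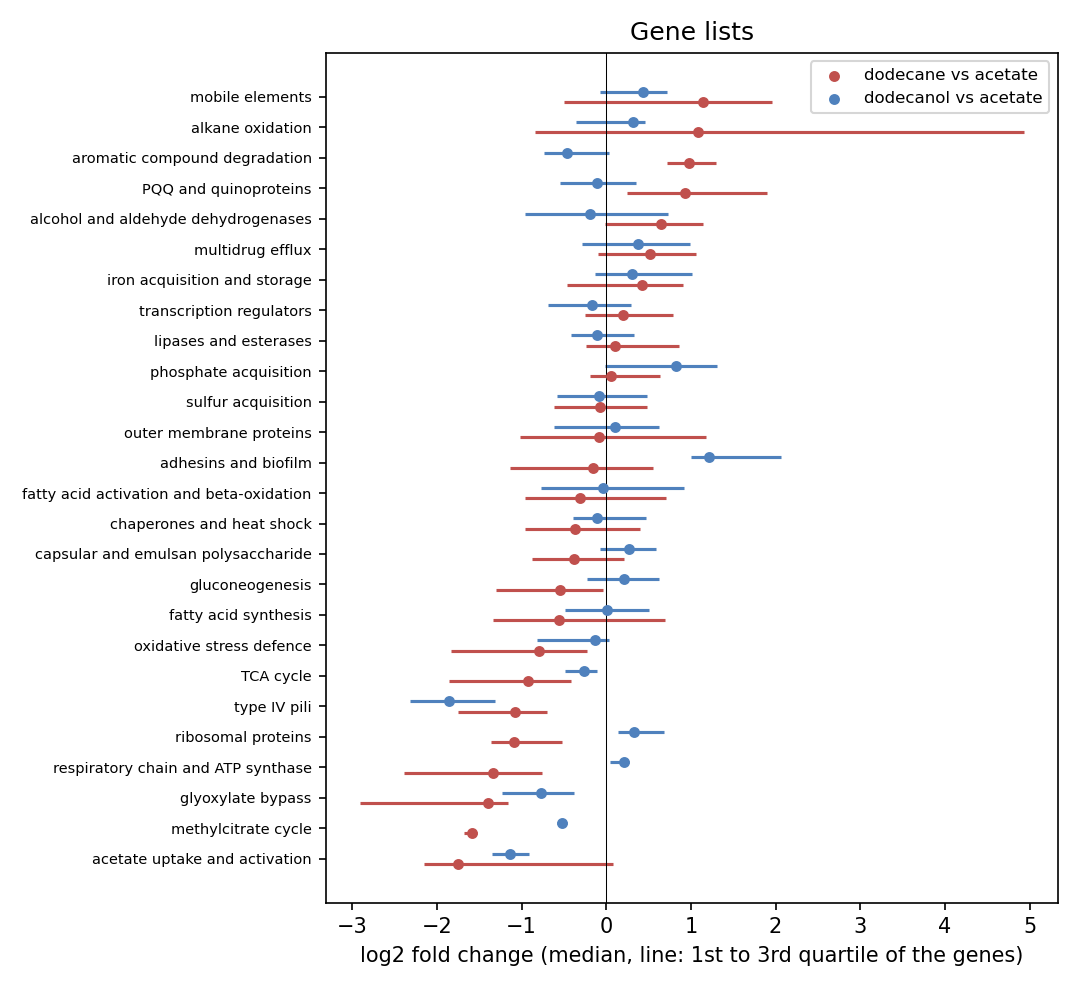
For each gene list (vertical axis), points give the median log2 fold change of its genes and lines run from the lower to the upper quartile (horizontal axis), for dodecane (red) and dodecanol (blue) against acetate. Respiratory chain and ATP synthase genes had a median of -1.34 on dodecane against acetate and of 0.21 on dodecanol against acetate.

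Genes changed at least 2-fold in the same direction by dodecane and dodecanol against acetate numbered 273, 139 higher and 134 lower. Independent lists of these sizes would share 62.3 and 58.2 genes. Groups simulated without any effect shared 0.04 and 0.01, which was fixed in advance, since hardly any gene is called without effects. Unrelated effects against common acetate libraries were not simulated. The genes higher on both included the alkane-1 monooxygenase peg.2514, the alcohol dehydrogenase peg.2264, the aldehyde dehydrogenase peg.2266 and the ectoine regulator peg.2961. Type IV pilus genes made up 16 of the 134 lower on both (Fisher's exact test, adjusted p = 4.52e-14). That test takes genes as independent, and the list had adjusted p = 0.396 and 0.465 with an estimated correlation on dodecane and dodecanol against acetate. Across genes, the fold changes of both comparisons correlated at 0.38 and shared a sign in 58.0% of genes. Simulated groups without effects, with all 9 libraries drawn anew and acetate common to both contrasts, gave 0.54 and 67.9%. Without effects these values come only from the spread between libraries and the common acetate group. They are therefore no benchmark for the observed 0.38 and 58.0%, and do not show that the responses share less than chance. The covariance was 0.49 against a simulated 0.06, a difference of 0.43. Both contrasts subtract acetate, so a gene that differs only on acetate also counts as shared. Neither the 273 genes nor this difference can tell such genes from a common response to dodecane and dodecanol. Part of the excess in shared genes may come from the common acetate libraries, which are too few to be split.

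Dodecane differed in the same direction from both other carbon sources, by at least 2-fold, in 613 genes, 369 higher and 244 lower. The monooxygenase peg.2514 and the ectoine regulator peg.2961 were also among the 273 shared genes. Both alkane-1 monooxygenases and the reductase peg.2776 were among the 369, as were 9 of the 24 aromatic degradation genes (Fisher's exact test, adjusted p = 0.0240). That test takes genes as independent, and camera gave the list adjusted p = 0.396 and 0.442 with an estimated correlation against acetate and dodecanol. The 244 lower genes held 32 of 57 ribosomal protein genes, 20 of 29 respiratory genes and 7 of 19 TCA cycle genes (adjusted p = 1.41e-20, 1.68e-15 and 0.00283, Fisher's exact test). For these 3 lists camera gave adjusted p = 0.50, 0.396 and 0.465 with an estimated correlation against acetate, and adjusted p = 0.442, 0.442 and 0.483 with an estimated correlation against dodecanol. They also held 5 of 15 gluconeogenesis, 6 of 21 oxidative stress and 3 of 5 methylcitrate genes (adjusted p = 0.0176 each, Fisher's exact test), and 3 of 143 transcription regulators, fewer than expected by chance (adjusted p = 0.0217, Fisher's exact test). For these 4 lists camera gave adjusted p = 0.396 to 0.72 with an estimated correlation against acetate, and adjusted p = 0.442 to 0.483 with an estimated correlation against dodecanol. Dodecanol differed in this way in 350 genes, 127 higher and 223 lower, with no list past Fisher's exact test (smallest adjusted p = 0.258 among higher and 0.351 among lower genes). The efflux genes peg.1050 and peg.1051 were among the 127. Under library size alone the 613 became 753 higher and 76 lower, and the 350 became 41 higher and 413 lower. Leaving out 1 library gave 490 (without AK3, 298 higher and 192 lower) to 641 (without AK4) in place of the 613. In place of the 350 it gave 300 (without AK6) to 408 (without AK4).

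**Figure D4:**
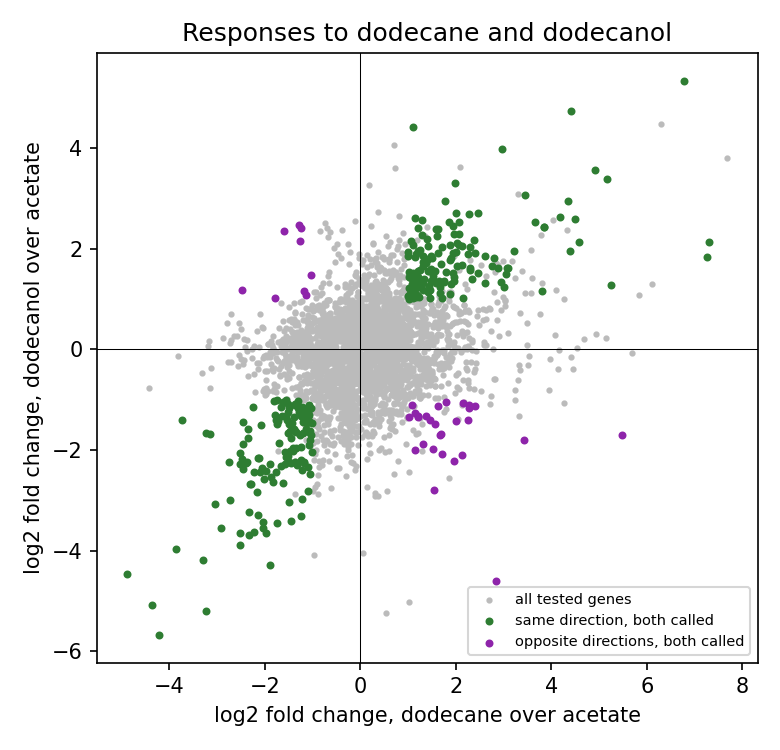
Each point is a gene, placed by its log2 fold change on dodecane against acetate (horizontal axis) and on dodecanol against acetate (vertical axis). The 273 genes changed at least 2-fold in the same direction are green, 37 changed in opposite directions are purple, and the rest of the 3178 tested genes are grey.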

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

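Only the test of counts left by the most abundant genes was chosen after its result was seen. On dodecane and dodecanol against acetate, 37 genes changed at least 2-fold in opposite directions, 28 of them higher and 9 lower on dodecane. All 37 also passed in dodecane against dodecanol, which restates how they were selected and is no separate evidence.

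The 37 genes drew attention because the same contrast with acetate gave opposite signs in both compounds, given at unmatched doses (1% v/v and 5 mM). Among named genes higher on dodecane, the log2 fold change of dodecane over dodecanol was 5.23 for peg.1070, named for the glycine cleavage P protein, 3.65 and 3.05 for the pilus tip genes peg.1725 and peg.1623, 3.39 for acetyl-coenzyme A synthetase peg.3093, 3.15 for porin B peg.2585 and 2.87 for aldehyde dehydrogenase peg.1064. Among those lower on dodecane it was -3.94 for the fimbrial gene peg.1985, -3.76 for the branched-chain amino acid carrier peg.2340, -3.66 for the organic hydroperoxide resistance gene peg.3022 and -3.65 for the short-chain oxidoreductase peg.999. For peg.1070, a gene at the edge of its scaffold, the value without dodecane library AK3 was 4.60.

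Scaling of the libraries could produce opposite signs near the 2-fold limit. The opposite calls were kept by 36 of the 37 genes under RLE and by 29 under library size alone, short of the share set beforehand for excluding scaling, so for the remaining genes scaling and the carbon source cannot be told apart. The number of such genes became 86 under library size alone and 57 without AK4. A single library as the whole source was argued against, since at least 28 of the 37 genes kept both calls whichever library was left out. The carbon source remains open as the biological explanation, with dose and growth state untested.

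Genes of ribosomal proteins, the respiratory chain with ATP synthase and the TCA cycle (105 genes) had a median log2 fold change of -1.14 on dodecane against acetate. Reads from genomic DNA were argued against: the density of the sparsest genes reached at most 0.0359 of the median density in a dodecane library, where 0.545 would be needed. Abundant genes taking the counts were argued against: the share of counts left beside the 24 genes among the 10 most abundant of any library had a lowest log2 ratio of -0.11 between a dodecane and an acetate library, where the members lay at -0.66 under library size alone. Relative to a trend on coding length and abundance they lay at -0.90 (quartiles -1.55 to -0.35). A lower growth rate on dodecane may be a candidate explanation, untested because growth rates were not analysed here, and on dodecanol against acetate the medians of the 3 lists were 0.33, 0.21 and -0.26.

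Other divisions of the libraries were refitted. For each pair of carbon sources the 6 libraries allow 10 divisions into 3 and 3, too few for a share under 0.05. The real division called 1737, 1441 and 1994 genes (dodecane against acetate, dodecanol against acetate, dodecane against dodecanol), and 1017, 764 and 1215 at least 2-fold. The highest of the other divisions called 0 in each, so the real one was the 1 division with as many. Every other division put libraries of both carbon sources in each group, which adds their difference to the spread within groups. Calls near 0 there were fixed by the design, so the comparison is no evidence for the real division. For the gene lists, 2, 8 and 1 of 10 divisions called as many lists as the real one (9, 2 and 11 lists, highest other 9, 6 and 10). The other divisions keep part of the carbon-source contrast, so these shares cannot weigh the list calls. List calls at the preset correlation remain weak evidence, since 0 lists were called with an estimated correlation. Among 100 divisions of the 9 libraries into 3 groups, the real one included, 3, 1 and 2 gave as many genes as the real one. The real counts were 273 for the shared response (highest other 293), 613 for dodecane apart (highest other 587) and 350 for dodecanol apart (highest other 580). Each share was under the 0.05 set beforehand, but the shares cannot exclude chance, as the make-up of the other divisions shows. The other divisions that gave any gene (3, 2 and 5) all kept 1 real group whole, and 2 of the 3 highest others exceeded the real count. These shares therefore reflect how rarely a division keeps a real group together, and are no separate evidence for the shared response or for genes apart.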

How the results depend on the processing

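Thinning all libraries to the total of AK7 was chosen after the data were seen. Counts of genes changed in each comparison stayed within 1.5 times of their reported values in every setting run, although library size alone moved the splits. The 37 genes with opposite changes became 86 under library size alone, and ran from 28 (without AK3) to 57 (without AK4). Without a fold limit the shared response became 623 genes, dodecane apart 1096 and dodecanol apart 842, since fewer genes were excluded. With an estimated correlation 0, 0 and 0 lists were called (dodecane against acetate, dodecanol against acetate, dodecane against dodecanol), and with fry, which tests another question, 20, 9 and 20. The ribosomal call for dodecanol against acetate was not among the 9. With each library left out, the lists for dodecanol against acetate ran from 1 (without AK8) to 3. Named genes kept direction and side of the threshold in 2981 combinations with a setting, lost a call in 34, gained one in 9 and changed sign in 14. The latter were genes that had not passed. Glucose dehydrogenase peg.472 on dodecane against acetate ran from -0.22 (without AK3) to 0.25 with each library left out, and passed at 0.63 under library size alone. With each library left out, peg.2111 on dodecanol against acetate ran from -0.11 (without AK8) to 0.68 (without AK7). On dodecanol against acetate, malate synthase G (peg.2347) gave -0.17 under library size alone, -0.0204 at a mean of at least 10 CPM, -0.0019 with limma-voom, -0.0065 with 2 groups and -0.0254 when thinned, and ran from -0.10 (without AK8) to 0.10 (without AK7). The wax ester synthase gene peg.400 gave 0.0013 under RLE and 0.00068 with DESeq2, and ran from -0.0734 (without AK9) to 0.0587 (without AK8). The cause was not tested. Unique and total reads were equal, so that setting moved nothing. No paired analysis was possible because the count columns carry no replicate number. Leaving out ribosomal and transfer RNA genes was not run, since the tables hold none, and a pseudocount for normalized values did not apply to counts. Depth limits low genes most in acetate library AK7, where 3 counts are 1.17 CPM.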

Other observations

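The neighbouring genes were noticed before they were tested on these data, and the prediction for the shuffled orders was written before that test. Malonate decarboxylase genes, whose products break down malonate, rose together on dodecane against acetate. All 9 genes from peg.1470 to peg.1478 (1652285 to 1658810 of scaffold NZ_KB849558) were called, with a mean log2 fold change of 3.15 and a range of 2.13 to 4.13. The 6 genes from the ectoine regulator peg.2961 to a permease, peg.2966 (76401 to 81447 of NZ_KB849559), had a mean of 4.01. The 4 genes from peg.2052 to peg.2055 (670297 to 674534 of NZ_KB849558), which hold fumarylacetoacetase, maleylacetoacetate isomerase and an aromatic amino acid transporter, had a mean of 4.21. In the other direction, 7 ATP synthase genes (peg.3053 to peg.3059) had a mean of -2.54, 4 cytochrome o oxidase genes (peg.1386 to peg.1389) a mean of -2.30, and 4 genes around an efflux pump (peg.1455 to peg.1458) a mean of -2.97.

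The hypothesis that neighbouring genes changed together was tested with the order of the genes. Log2 fold changes of 3173 adjacent pairs correlated at 0.42 across genes, which are not independent replicates, and the highest of 10000 shuffled orders gave 0.0665, so chance order was argued against. There were 9 runs of at least 4 neighbours changed at least 4-fold in the same direction, and 1000 shuffled orders gave 0.035 on average and 1 at most. The remaining runs were peg.386 to peg.390 (mean 3.00), peg.663 to peg.666 (4.15) and peg.1868 to peg.1871 (3.37), mostly of hypothetical proteins. Shared transcripts may account for this, but the tables name no strand, and reads over the ends of overlapping genes could add to the correlation of 0.42.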
